A study of Mus musculus with 13 samples.

How the data were processed

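Total RNA from the hearts of 13 male C57BL/6 mice was hybridised as biotin-labelled cRNA to Illumina mouse expression BeadChips, per the labels. The labels give 3 groups: 5 mice injected with PBS (control), 5 injected with doxorubicin, and 3 given the receptor-Fc fusion protein sAcvR2B-Fc 48 hours before doxorubicin. Hearts were taken 20 hours after the doxorubicin or PBS injection. The labels describe no group that received sAcvR2B-Fc without doxorubicin, so no such group was analysed here. Each array was taken as 1 mouse.

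The first deposited table holds 1 signal intensity per probe and array on a linear scale, with no scaling between arrays. Its lowest value on each array lay between 79.2 and 102, so no background had been subtracted. The deposited table also gives, per the file headers, a detection p-value for each signal. The software behind these values is not given in the sources used here. The columns carry sample names that the labels repeat for each sample, and arrays were assigned to samples through these names. The second deposited table, the series matrix, holds intensity values that the authors had processed further. Judged from its values, it is on a linear scale, background-subtracted and quantile-normalized: its column medians lay between 6.8 and 6.9, and the steps behind it are not given in the sources used here. The series matrix was used only in alternatives, with values under 1 set to 1 before taking log2.

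Each series matrix column was set against every column of the non-normalized table by Spearman correlation. Each matched 1 array with a correlation of at least 0.999994, while the next best match reached at most 0.903779. For 5 of the 13 samples both tables named the same array. For 8 samples they named different arrays, and for 6 of these the array belonged to another group. The non-normalized table had been chosen as the source before the data were examined, and its sample names were kept. The sources used here do not settle which table is right, so the counts of called genes under the other assignment stand beside each comparison. Calls of lists under it are counted once, over all comparisons.

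Signals were background-corrected with normexp, using the detection p-values to estimate the background, quantile-normalized and log2-transformed with limma's neqc (limma 3.58.1, R 4.3.3, offset 16). Of 45281 probes, 18693 had a detection p-value under 0.05 on at least 3 arrays. Probes were named from the platform annotation, updated through gene identifiers to the GRCm38.p6 gene table, which held 99.72% of the identifiers. Of all probes, 34885 had 1 symbol, 18 had several and 10378 were unnamed here. Each gene was represented by its passing probe with the highest mean over the 13 arrays, which gave 10410 genes, 3828 of them with more than 1 passing probe. No coordinates were used.

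Median raw signals per array ranged from 101.5 to 136.3, and 15989 to 17939 probes per array were detected. No pair of arrays held identical values, and correlations between arrays over the tested genes ran from 0.97 to 0.993. The number of arrays limits the precision. On simulated data with the real gene means and spreads, 200 of 10410 genes were changed. A log2 change of 1 was recovered for 92.5% of such genes in doxorubicin against control. The share was 83.6% in the pre-treated against the doxorubicin group and 80.6% in the pre-treated group against control. The simulated genes varied independently, so these shares leave out the structure across arrays found in the real data.

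The 3 groups were fitted in 1 linear model with limma (lmFit and eBayes, two-sided moderated test) without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called at an adjusted p under 0.05. Values are given as log2 differences with their SE from the model, or as group means with SD. Replicate numbers in the labels were not used to pair mice. A gene below the detection threshold on every array of its lower group is given as at least N-fold. That bound sets the higher group's mean against the lower group's mean of the lowest detected signal of each array, or of the gene's own signal where higher.

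Fixed before the data were examined were 25 gene lists and 16 cell type marker lists. Lists with at least 5 tested members were compared with all other genes by camera at a preset correlation of 0.01, and again with an estimated correlation. Fry tested each list on its own, in one direction and in either direction. Adjusted p-values of lists cover all lists of a comparison. A shift of doxorubicin-changed genes was tested by an exact permutation over the 56 splits of the 8 doxorubicin-treated arrays, with the calls made anew in each split.

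The text names up to 10 called genes with the largest increase and up to 10 with the largest decrease per comparison whose groups did not overlap, without clone or predicted names. It adds up to 4 members of each list with the smallest adjusted p, and 15 genes named in advance for the receptor pathway, the p53 response, the drug's targets and cardiac stress. Of these 15, Mstn, Gdf11, Inhbb, Fst, Fstl3, Gdf15, Top2a and Top2b had no probe that passed the filter.

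Alternatives fixed in advance were the series matrix, no background correction, median scaling, cyclic loess, no or a stricter detection filter, each probe on its own, an intensity trend with robust settings, array weights, 2-group fits, the replicate number as a block, and leaving out each array. Alternatives chosen after seeing the data were the exchange of sample assignments between the tables, the arrays that both tables place in the same group, array splits as covariates, and an exact permutation of list medians. A BeadChip block was not fitted, because the column names used here give no chip.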

Results

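Gene expression was measured in the hearts of 13 mice on single-colour Illumina arrays. Control mice (n = 5) received PBS. Doxorubicin, an anthracycline chemotherapy drug that damages DNA and is toxic to the heart, was given alone to 5 mice. Another 3 mice received sAcvR2B-Fc 48 hours before doxorubicin. This soluble form of activin receptor 2B binds activins, myostatin and related ligands and keeps them from their receptors. All hearts were taken 20 hours after the doxorubicin or PBS injection. Detected probes numbered 15989 to 17939 per array, and 10410 genes were tested.

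The deposited tables disagreed on which array belongs to which mouse for 8 of the 13 samples, and for 6 of them on the group. Values here follow the sample names of the non-normalized table. Under the series matrix names, 3 of the list calls given below held, 13 ended and 1 reversed, on the values of either table.

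The first comparison asked what doxorubicin alone changed in the heart. The largest increases were in S100a9 and S100a8, which encode the calprotectin subunits abundant in neutrophils. S100a9 was 6.92-fold higher after doxorubicin (log2 difference 2.79 ± 0.23, SE, n = 5 and 5, adjusted p = 7.9e-05), and S100a8 was 5.87-fold higher (2.55 ± 0.27, adjusted p = 0.000993). Both were detected on all 5 doxorubicin arrays and on 1 of the 5 control arrays, so these folds rest on control signals near background. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose 5.64-fold (2.50 ± 0.32, adjusted p = 0.00606). The oligoadenylate synthetase family members Oasl2, Oas2 and Oas1g, which are known to be induced by interferon, rose 2.79-, 2.54- and 2.49-fold. The protease gene Usp18, which acts on a ubiquitin-like interferon-induced protein, rose 2.57-fold, the RNA sensor gene Dhx58 rose by 1.20 ± 0.17 and the guanylate-binding protein gene Gbp10 by 1.20 ± 0.22 on the log2 scale. Some of these rest on 1 probe of several: the other Usp18, Oas1g and Oasl2 probes stood at 0.53, 0.52 and 1.30 and were not called over all probes. Of the other 2 Dhx58 probes 1 was called (1.35) and 1 was not (0.48), while both other Cdkn1a probes were called (2.06 and 2.29).

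The largest decrease was in Dnaaf3, an assembly factor of axonemal dyneins, which was 2.69-fold lower (log2 difference -1.43 ± 0.20, adjusted p = 0.011). The water channel gene Aqp4 was 1.96-fold lower (-0.97 ± 0.16), and Ctf1, which encodes the cytokine cardiotrophin, was 1.86-fold lower (-0.89 ± 0.15). Smaller decreases were found for the mesenchymal homeobox gene Prrx1 (-0.78 ± 0.12), the cGMP-dependent protein kinase gene Prkg1 (-0.64 ± 0.10, with doxorubicin replicate 2 apart from the other 4), and for Tmem86a, Igdcc4 and Rtn2. The other probes of Prrx1 (-0.43 and -0.48) and Prkg1 (-0.32) were not called. The Ras pathway scaffold gene Cnksr1 rose 2.31-fold (1.21 ± 0.18). Mdm2, another p53 target, did not pass the test over all genes (0.40 ± 0.16, adjusted p = 0.302), nor did the natriuretic peptide genes Nppa (0.08 ± 0.19) and Nppb (-0.83 ± 0.59). The receptor genes Acvr2a (0.25 ± 0.17) and Acvr2b (-0.20 ± 0.10) and the activin subunit gene Inhba (0.00 ± 0.18) did not pass either. Acvr2a was detected on 2 of 5 control, 3 of 5 doxorubicin and 1 of 3 pre-treated arrays, and Inhba on 4, 4 and 3.

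**Figure D1:**
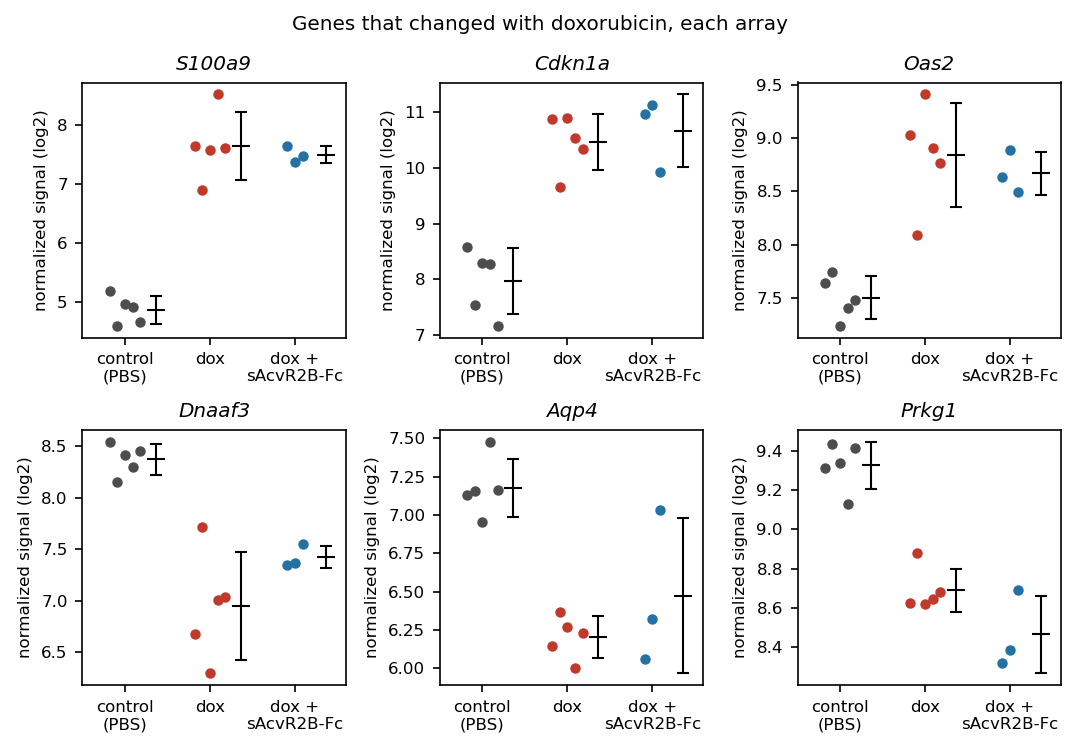
Normalized log2 signal of 6 genes on each array, with control (n = 5), doxorubicin (n = 5) and doxorubicin with sAcvR2B-Fc (n = 3) on the horizontal axis. Points are arrays, and bars show the group mean and SD. S100a9 had a mean of 4.86 in control hearts and 7.65 after doxorubicin.

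Among the fixed lists, neutrophil markers rose after doxorubicin (6 tested, median log2 difference 0.57, camera adjusted p = 1.4e-08). This call held with an estimated correlation (adjusted p = 0.0444 with an estimated correlation). S100a8 and S100a9 were called among all genes, and 5 of the 6 markers rose when adjusted over the list alone, including Lcn2 (0.68 ± 0.24, detected on 3 of the 5 control arrays) and Retnlg, which was detected on 0 control arrays and 2 doxorubicin arrays and is given no fold. Of 27 p53 targets, 24 had a positive difference, with a median of 0.38 (camera adjusted p = 1.55e-11). The adjusted p = 0.265 with an estimated correlation. Only Cdkn1a was called among all genes, and 13 targets rose when adjusted over the list alone, among them Phlda3 (1.31 ± 0.25) and Ddit4 (1.03 ± 0.25). The interferon and antigen presentation list had a median of 0.69 over 28 genes (camera adjusted p = 3.8e-11; adjusted p = 0.311 with an estimated correlation). Oasl2 and Usp18 were called, and 15 members rose and 2 fell when adjusted over the list alone, with Irf7 at 1.54 ± 0.30 and Ifit3 at 1.55 ± 0.31 (control replicate 3 apart from the other 4). Doxorubicin replicate 2 had the lowest Irf7, Ifit3, Oasl2 and Cdkn1a of its group. On the second principal component of all arrays it lay at 8.77, near the controls (10.2 to 16.1) and apart from the other doxorubicin arrays (-22.8 to -2.19). Without it the interferon median was 0.87 and the p53 median 0.40.

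NRF2 antioxidant genes also lay higher after doxorubicin by camera, with a median of 0.35 over 20 genes (adjusted p = 1.46e-06; adjusted p = 0.265 with an estimated correlation). Gpx3, a secreted glutathione peroxidase, was called (0.59 ± 0.10) and was the 1 member that rose when adjusted over the list alone, while Mgst1 (0.69 ± 0.23) and Nqo1 (0.37 ± 0.13) did not pass. The NF-kB list (median 0.22, adjusted p = 0.0192; adjusted p = 0.396 with an estimated correlation) contained 1 called gene, the oncostatin M receptor gene Osmr (0.70 ± 0.12), and 3 of its 20 genes rose when adjusted over the list alone. Glucocorticoid-responsive genes had a median of 0.16 (adjusted p = 0.0192; adjusted p = 0.452 with an estimated correlation), with 0 of 23 called by limma and 1, Ddit4, when adjusted over the list alone.

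Calcium handling and ion channel genes lay lower, with a median of -0.17 and 16 of 17 negative (camera adjusted p = 0.00208; adjusted p = 0.311 with an estimated correlation). None was called among all genes by limma, and 3 fell when adjusted over the list alone; the potassium channel genes Kcnd2, Kcnip2 and Kcnh2 had differences of -0.78 ± 0.23, -0.66 ± 0.20 and -0.48 ± 0.15. Smooth muscle and pericyte markers had a median of -0.20, with 11 of 11 negative (adjusted p = 0.00303; adjusted p = 0.376 with an estimated correlation), and 1 fell when adjusted over the list alone. The pericyte channel gene Kcnj8 stood at -0.44 ± 0.09. Erythroid markers had a median of -0.46 (8 genes, adjusted p = 0.02; adjusted p = 0.396 with an estimated correlation). The erythroid call ended without control replicates 1 or 3 or doxorubicin replicate 5 (highest adjusted p = 0.11), the glucocorticoid call without control replicate 3 or doxorubicin replicates 1 or 3 (0.136), and the NF-kB call without control replicate 4 or doxorubicin replicate 5 (0.11). Oxidative phosphorylation (45 genes), sarcomere (22 genes) and cell cycle genes (20 genes) did not pass by camera, with adjusted p = 0.79, 0.288 and 0.6. Fry, which tests a list without setting it against other genes, called 7 of 34 lists in one direction and 9 in either direction.

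In all, limma called 25 of 10410 genes, 17 higher and 8 lower after doxorubicin, and 1275 had an unadjusted p under 0.05. Under the sample names of the series matrix limma called 0 genes, with 164 at an unadjusted p under 0.05 (178 on series matrix values); 0 were called on the 7 arrays that both tables place in the same group, with 732. The count was 3, 6, 8 and 332 without doxorubicin replicates 1, 4, 3 and 2, was 13, 5, 12 and 7 without control replicates 2, 3, 4 and 5, and was 42 without pre-treated replicate 2. S100a9, S100a8 and Cdkn1a were called whichever array was left out. The others were called in 3 (Gbp10) to 12 (Dhx58 and Dnaaf3) of the 13 fits that left out 1 array, with Osmr and Rtn2 in 4, Gpx3 and Tmem86a in 5, and Oasl2, Usp18, Oas1g, Aqp4 and Ctf1 in 6.

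The second comparison set mice pre-treated with sAcvR2B-Fc before doxorubicin against mice given doxorubicin alone. The largest increase was in Vsig4, a complement receptor of tissue-resident macrophages, which was 7.09-fold higher with pre-treatment (log2 difference 2.83 ± 0.27, SE, n = 3 and 5, adjusted p = 0.00015). The largest decreases were in Ccl21a and Ccl21c, which encode a chemokine of lymphatic vessels and lymphoid tissue. Ccl21a was 7.16-fold lower (-2.84 ± 0.24, adjusted p = 7.87e-05) and Ccl21c was 6.74-fold lower (-2.75 ± 0.29, adjusted p = 0.000432). Kcne1, the regulatory subunit of the slow delayed rectifier potassium channel, was 5.20-fold lower (-2.38 ± 0.22, adjusted p = 0.000137) and was detected on 2 of the 3 pre-treated arrays. Its other passing probe stood at -0.02 (adjusted p = 0.975 over all probes), so the decrease rests on 1 of 2 probes. Masp1, a serine protease of the lectin complement pathway, was 2.54-fold lower (-1.34 ± 0.14, adjusted p = 0.000432).

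Ccl21a, Ccl21c and a predicted copy of them are near-identical in sequence, so their probes may not be told apart, and they count as 1 signal seen on 4 probes. The C-type lectin gene Clec10a was at least 1.28-fold lower with pre-treatment (adjusted p = 0.0348), being detected on 4 of the 5 doxorubicin arrays (with replicate 5 lying apart from the other 4 in level) and on none of the 3 pre-treated arrays. Tmem116 (1.00 ± 0.16, adjusted p = 0.0294) and Dipk1b (0.68 ± 0.11, adjusted p = 0.0482) rose; the other 2 Tmem116 probes stood at 0.08 and 0.33 and were not called. The doxorubicin-responsive genes Cdkn1a (0.21 ± 0.36), S100a9 (-0.15 ± 0.26) and S100a8 (-0.22 ± 0.31) did not pass the test between these groups. Nppa (-0.62 ± 0.22, adjusted p = 0.37) and Nppb (0.10 ± 0.68) did not pass, nor did Mdm2 (0.09 ± 0.18), Acvr2a (-0.28 ± 0.20), Acvr2b (0.12 ± 0.11) and Inhba (-0.06 ± 0.21).

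**Figure D2:**
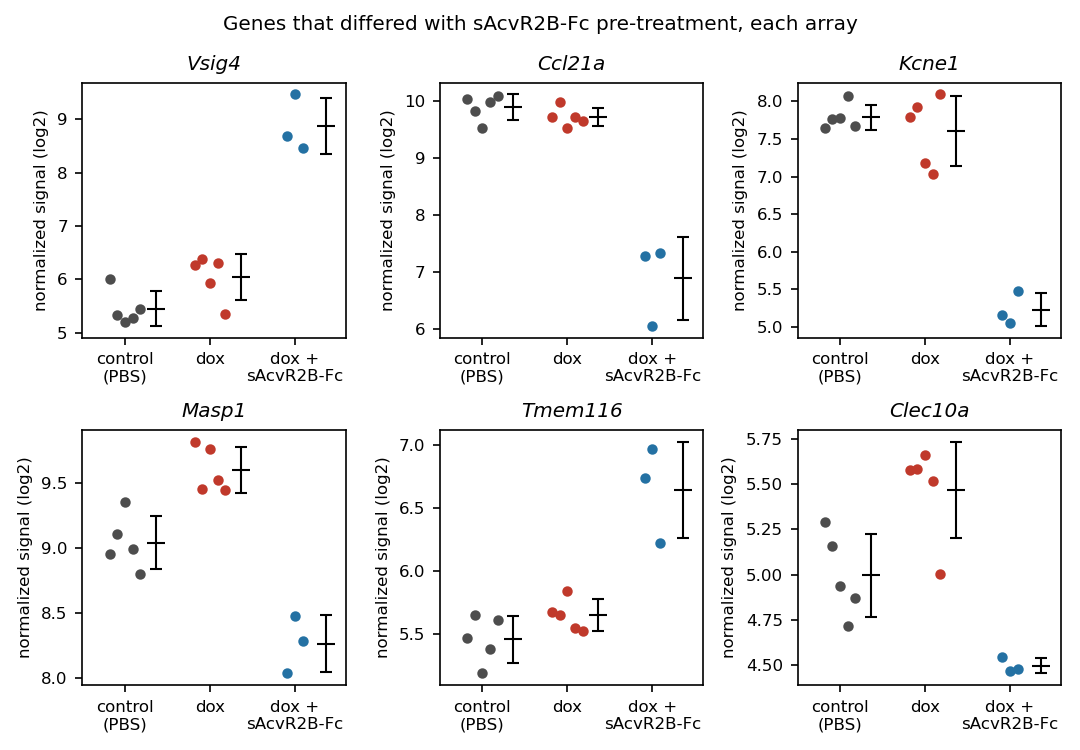
Normalized log2 signal of 6 genes on each array, with control (n = 5), doxorubicin (n = 5) and doxorubicin with sAcvR2B-Fc (n = 3) on the horizontal axis. Points are arrays, and bars show the group mean and SD. Vsig4 had a mean of 6.05 after doxorubicin and 8.87 with pre-treatment, while Ccl21a fell from a mean of 9.73 to 6.89.

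Of the fixed lists, camera called the interferon and antigen presentation list, which lay lower with pre-treatment (28 genes, 27 negative, median -0.36, adjusted p = 2.18e-07). The adjusted p = 0.908 with an estimated correlation. Fry in one direction gave this list an adjusted p = 0.666 and called 0 of 34 lists. The doxorubicin arrays enter both this comparison and that of doxorubicin against control. The list's rise there and its fall here are therefore not independent. By limma 0 of its genes were called, and 1 fell when adjusted over the list alone: the class II antigen presentation gene H2-Aa (-1.78 ± 0.42, adjusted p = 0.208 over all genes). Ifi47 stood at -1.04 ± 0.37, Oasl2 at -0.84 ± 0.31 and the chemokine gene Cxcl9 at -0.53 ± 0.20. The activin, myostatin and TGF-beta pathway list did not pass by camera (20 genes, median -0.22, adjusted p = 0.111), and 0 of its members were called by limma over all genes or adjusted over the list alone. Its members with the smallest p included Smad1 (-0.77 ± 0.21), Bmpr2 (-0.29 ± 0.09) and Bmp4 (-0.37 ± 0.15). SMAD target genes did not pass (18 genes, median -0.11, mean 0.0019, adjusted p = 0.866), and Id1 (0.63 ± 0.16) was the 1 that rose when adjusted over the list alone. By fry in either direction it was the 1 list of 34 that passed (adjusted p = 3.69e-05). Of 23 glucocorticoid-responsive genes 2 rose when adjusted over the list alone, Sgk1 (0.66 ± 0.12) and Nfkbia, while the list did not pass (median 0.16, adjusted p = 0.121). The p53, neutrophil and NRF2 lists had medians of 0.05, 0.04 and 0.02 and did not pass; camera ranked all 3 downward, opposite to their medians.

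In all, limma called 9 genes, 3 higher and 6 lower with pre-treatment (1 and 6 with median scaling), and 1181 had an unadjusted p under 0.05. Under the sample names of the series matrix limma called 0 genes, with 324 at an unadjusted p under 0.05 (349 on series matrix values), and Vsig4 changed sign (-0.055, and -0.23 on series matrix values); on the 7 arrays that both tables place in the same group, 1 of them pre-treated, 4 were called. That lone array was assumed to vary like those of the other groups. Leaving out 1 array at a time gave 6 to 11 called genes, and Vsig4, Ccl21a, Ccl21c, Kcne1 and Masp1 were called each time. Tmem116 was called in 7 of the 13 fits, Clec10a in 3 and Dipk1b in 2 (highest adjusted p = 0.175, 0.175 and 0.274).

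The third comparison set pre-treated and doxorubicin-injected mice against control mice. Vsig4 was 10.7-fold higher than in controls (log2 difference 3.42 ± 0.27, SE, n = 3 and 5, adjusted p = 2.49e-05). Cdkn1a was 6.52-fold higher (2.70 ± 0.36, adjusted p = 0.00312), S100a9 was 6.24-fold higher (2.64 ± 0.26, adjusted p = 0.000159) and S100a8 was 5.04-fold higher (2.33 ± 0.31), both against controls detected on 1 of 5 arrays. The p53 target Phlda3 rose 2.95-fold (1.56 ± 0.29), the chemokine gene Ccl6 rose 2.93-fold (1.55 ± 0.25, detected on 3 of 5 control arrays) and the Ras-like gene Rasl10a rose 3.37-fold (1.75 ± 0.31). Ccl21a was 8.07-fold lower (-3.01 ± 0.24, adjusted p = 2.49e-05), Ccl21c 7.98-fold lower and Kcne1 5.90-fold lower (-2.56 ± 0.22). The other Kcne1 probe stood at -0.03 (adjusted p = 0.972 over all probes).

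Of the interferon and antigen presentation list, 3 class II genes fell: H2-Aa by 4.73-fold (-2.24 ± 0.42, adjusted p = 0.0239), H2-Ab1 by 2.69-fold (-1.43 ± 0.26) and H2-Eb1 by 2.46-fold (-1.30 ± 0.26). They were called in 9, 9 and 5 of the 13 fits that left out 1 array. H2-DMb1, chosen after its values were seen, fell as well (-1.18 ± 0.14, detected on 2 of 3 pre-treated arrays) and was called in all 13. The kinase anchoring protein gene Akap5 was at least 3.78-fold lower, being detected on none of the 3 pre-treated arrays (adjusted p = 0.0212). The stem cell factor receptor gene Kit (-1.75 ± 0.30), the integrin gene Itgb6 (-1.61 ± 0.29), the cytokine gene Il16 (-1.35 ± 0.30, with its other probe at -0.12) and Kcnd2, a subunit of the transient outward potassium channel (-1.59 ± 0.27, with its other probe at -0.70 and not called), also fell. Dcxr (1.36 ± 0.30), Pdxp (1.38 ± 0.30, detected on 4 of 5 control arrays) and Gbp10 (1.29 ± 0.26) rose. Of the 13 fits, Dcxr and Pdxp were called in 2, Il16 in 3 and Gbp10 in 7 (highest adjusted p = 0.216, 0.208, 0.201 and 0.171), Akap5, Itgb6, Phlda3 and Rasl10a in 9, Kit in 10 and Kcnd2 in 12. Nppa (-0.54 ± 0.22), Nppb (-0.73 ± 0.68), Mdm2 (0.49 ± 0.18), Acvr2a (-0.03 ± 0.20), Acvr2b (-0.08 ± 0.11) and Inhba (-0.06 ± 0.21) did not pass.

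Of 27 p53 targets, Cdkn1a, Phlda3 and Dcxr were called and 14 rose and 1 fell when adjusted over the list alone (median 0.38, camera adjusted p = 2.84e-06; adjusted p = 0.42 with an estimated correlation). Neutrophil markers had a median of 0.66, with S100a8 and S100a9 called and 5 of 6 higher when adjusted over the list alone (camera adjusted p = 8.26e-06; adjusted p = 0.151 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.42 (adjusted p = 0.000867; adjusted p = 0.42 with an estimated correlation). The kinase gene Sgk1 (0.81 ± 0.12) and the NF-kB inhibitor gene Nfkbia (0.84 ± 0.15) were called, and 9 of 23 rose when adjusted over the list alone. Of 20 NRF2 genes 6 rose when adjusted over the list alone and 0 were called by limma over all genes (median 0.24, camera adjusted p = 0.00102; adjusted p = 0.42 with an estimated correlation). Nfkbia, Icam1 (0.75 ± 0.15) and Osmr (0.72 ± 0.14), called in 9, 8 and 6 of the 13 fits that left out 1 array, were called in the NF-kB list, which did not pass by camera (adjusted p = 0.0503), and 6 of its 20 genes rose when adjusted over the list alone.

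Activin, myostatin and TGF-beta pathway genes lay lower by camera, with a median of -0.08 over 20 genes, 15 of them negative (adjusted p = 0.0306; adjusted p = 0.234 with an estimated correlation). By limma 0 were called over all genes and 2 fell when adjusted over the list alone, Smad1 (-0.75 ± 0.21) and the bone morphogenetic protein receptor gene Bmpr2 (-0.31 ± 0.09). Macrophage markers had a median of 0.31 (15 genes, adjusted p = 0.0247; adjusted p = 0.784 with an estimated correlation), with 0 called by limma and 4 higher when adjusted over the list alone, among them C1qb (0.80 ± 0.19) and Fcgr1 (0.83 ± 0.21, detected on 2 of 5 control arrays). Erythroid markers had a median of -0.63 (8 genes, adjusted p = 0.0247; adjusted p = 0.489 with an estimated correlation), with 4 lower when adjusted over the list alone, among them Alas2 (-1.35 ± 0.40). The pathway call ended without control replicate 1 or pre-treated replicates 2 or 3 (highest adjusted p = 0.117), the macrophage call without control replicates 4 or 5 or pre-treated replicate 2 (0.479), and the erythroid call without pre-treated replicate 3 (0.116). Under the series matrix names the macrophage median was -0.25 (adjusted p = 0.0134), and -0.26 on series matrix values. The interferon and antigen presentation list did not pass (median 0.36, mean 0.13, adjusted p = 0.326). Its 3 called genes were H2-Aa, H2-Ab1 and H2-Eb1, all lower, and 5 members rose and 5 fell when adjusted over the list alone. Of 18 SMAD targets Hey1 fell (-0.71 ± 0.16, with control replicate 1 apart from the other 4), and 1 rose and 2 fell when adjusted over the list alone. Hey1 was called in 3 of the 13 fits that left out 1 array (highest adjusted p = 0.193). By fry this list passed in either direction (adjusted p = 3.3e-05). Fry called 16 of 34 lists in either direction and 7 in one direction.

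**Figure D3:**
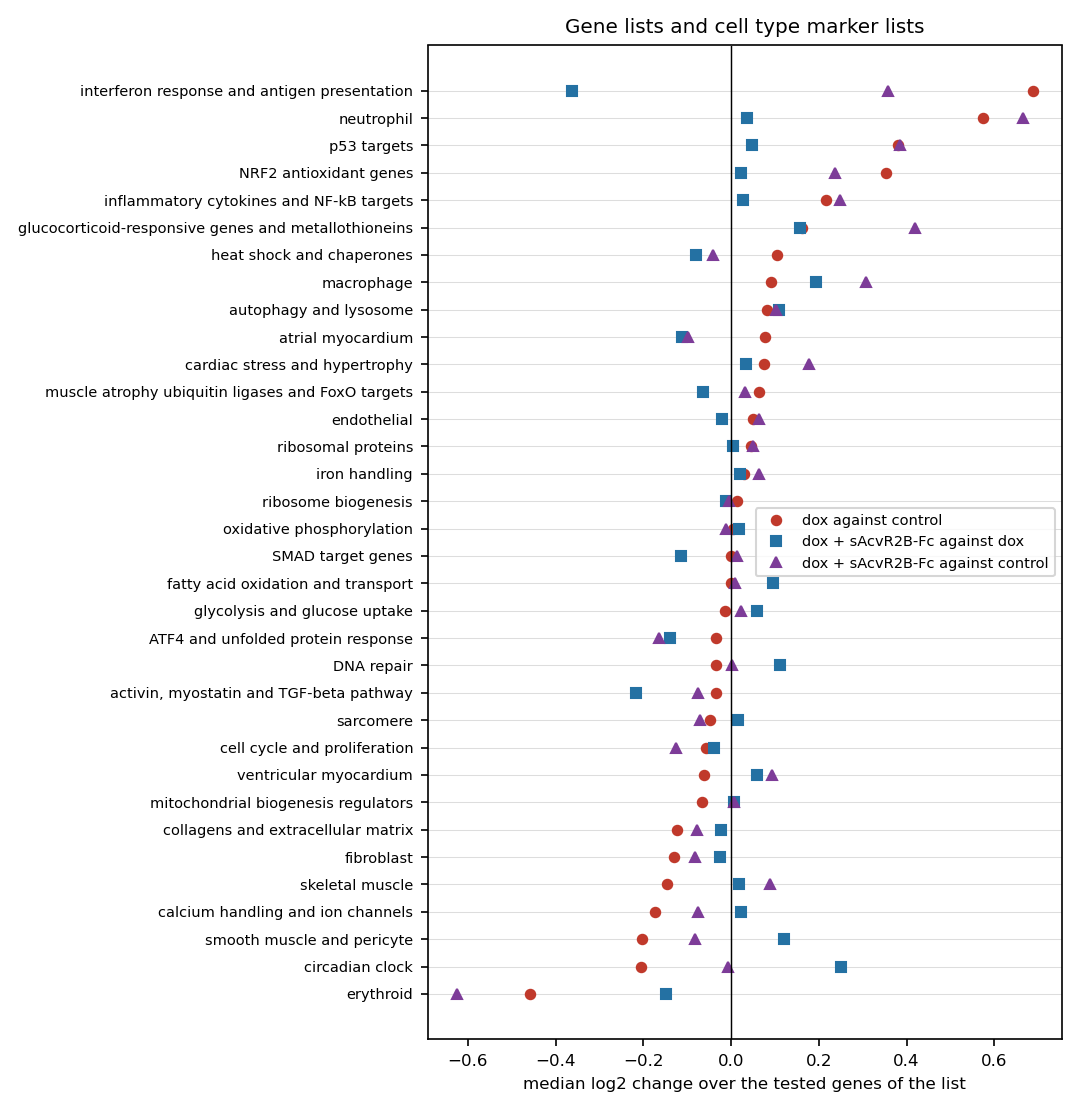
Median log2 difference over the tested genes of each list with at least 5 tested members, in the 3 comparisons. Each symbol is 1 comparison and 1 list, and the vertical line marks 0. The interferon and antigen presentation list lay at 0.69 for doxorubicin against control and at -0.36 for the pre-treated against the doxorubicin group. Both of these comparisons share the doxorubicin arrays.

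In all, limma called 128 genes, 73 higher and 55 lower than in controls (42 and 53 with median scaling), and 1900 had an unadjusted p under 0.05. Under the sample names of the series matrix limma called 0 genes, with 358 at an unadjusted p under 0.05 (361 on series matrix values), and 6 were called on the 7 arrays that both tables place in the same group, with the 1 pre-treated array again assumed to vary like the others. Without control replicates 1, 2, 3 and 4 the count was 81, 26, 25 and 67, without pre-treated replicates 1, 2 and 3 it was 37, 28 and 58, and without doxorubicin replicates 1, 2 and 4 it was 70, 294 and 77. Of the other passing probes of called genes, 56 of 64 had the sign of the chosen probe, values near 0 such as that of Kcne1 included; 8 probes of 5 genes, among them Nfkbia, had the opposite sign and none of these was called.

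The fourth comparison asked whether genes changed by doxorubicin lay closer to control with pre-treatment. Over the 25 called genes, the median log2 difference between the pre-treated and the doxorubicin group, signed so that a negative value is towards control, was -0.15. It was towards control for 72% of them. The doxorubicin arrays enter both the calls and the shift, which without any effect pulls the median below 0 and raises this share. What share no effect would give was not computed. Over all 56 splits of the doxorubicin-injected arrays into groups of 5 and 3 the median of this shift was -0.10, from -0.37 to 0.38. In simulated data with 200 genes changed by 2 log2 units the shift was -0.0132 for no effect and -1.98 for a full return to control. The simulated genes varied independently, without the structure across arrays seen in the data. The 25 called genes had a median change of 0.972 log2 units in size. The simulated values therefore do not show what either case would give here. The exact permutation test over 56 splits gave a one-sided p = 0.446 and a two-sided p = 0.893. On simulated data this exact permutation test gave a one-sided p = 0.5 even for a full return to control, so its p says little here. The calls were also made from 3 doxorubicin arrays and the shift taken from the other 2. Over the 9 of 10 splits with any call the median was 0.08, with values from -0.59 to 0.29. Simulated data gave -1.99 for a full return and 0.0028 for no effect. The splits with the most calls all gave positive values, from 0.11 to 0.29. Splits with 2 to 6 calls ran from -0.59 to 0.08, and the split at the median had 2 calls. The value therefore depended on which doxorubicin arrays made the calls, so this median does not decide whether the genes lay closer to control.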

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

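Chosen only after the result was seen were the tests of other splits of the arrays, of the sample names, of the array splits as covariates, and of macrophages as a source.

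Of 174 sets of 5 arrays tested for a single array far from the rest, 7 had one (4.02%, where chance gives about 5%), and 3 of the 7 were doxorubicin replicate 2. In that replicate Prkg1 was at 8.88 (log2, next highest 8.68), Nppa at 14.2 (13.4) and Akap5 at 7.16 (5.59). Ifit3 was at 8.61 in control replicate 3 (next lowest 9.45), and Clec10a at 5.00 in doxorubicin replicate 5 (5.52). Hey1 was at 9.00 in control replicate 1 (9.38) and at 8.62 in doxorubicin replicate 4 (9.13).

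Of 2817 probes that had no symbol or several, and so entered no comparison, limma called 4 in doxorubicin against control (3 higher), 2 in the pre-treated against the doxorubicin group (0 higher) and 18 in the pre-treated group against control (8 higher).

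The deposited tables named different samples for the same array in 8 of 13 samples. Over the 3 comparisons the names of the non-normalized table gave 162 calls, and 2 of 100 assignments of the arrays to groups of 5, 5 and 3 gave as many, these names included (highest 393). This argues against names in that table that are unrelated to the groups. The names of the series matrix gave 0 calls by limma, so 100 of 100 assignments necessarily gave as many, and 87 of 99 random ones also gave 0. That count decides nothing about the series matrix. A single wrong name in either table stays open, and the number of calls was not used to choose the names.

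For doxorubicin against control, 1 of 100 drawn splits of the arrays gave as many called genes, the real one included (25 genes, highest other 17). For the pre-treated against the doxorubicin group it was 2 of 56 (9 genes, highest other 309). For the pre-treated group against control it was 2 of 56 (128 genes, highest other 274). These shares lay under 0.05 with the sample names used here, which argues against chance. Chance is not excluded. The first draw did not cover all possible splits, and the splits take the sample names as given. For each of the other comparisons 1 other split gave more genes than the real one. The split with 309 set doxorubicin replicate 5 and pre-treated replicates 2 and 3 apart and the split with 274 set control replicates 1, 2 and 3 apart, which points to a structure of the arrays that crosses the groups. With that structure as a covariate the real comparisons gave 9 and 184 genes. The covariate was drawn from the spread within groups and takes up part of it by construction. These counts therefore do not decide whether the structure was the cause. For called lists chance cannot be excluded: 11 of 100, 49 of 56 and 9 of 56 splits gave as many as the real 9, 1 and 7 lists, with highest others of 14, 12 and 9.

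That structure held 32% of the variance within groups, with control replicates 4 and 5, doxorubicin replicate 5 and pre-treated replicates 2 and 3 on one side. Over its range 352 of 10410 genes moved by at least 1 log2 unit, 328 of them downward, such as Sdhd (-2.48) and Dld (-2.43). For the tested cell types tissue composition is argued against, since the largest median slope of such a list was 0.244 (smooth muscle and pericyte). Marker lists with under 5 tested members, among them adipocyte and lung epithelium, were not examined, so these sources stay open. Slopes of a gene's 2 brightest probes correlated at 0.102 across 3828 genes, against 0.609 for doxorubicin against control, which is consistent with a technical effect on single probes. Array brightness stays open (Pearson r = -0.444, permutation p = 0.128; Spearman rho = -0.192, p = 0.528; r = -0.461 without the 2 farthest of 13 arrays).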

How the results depend on the processing

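The exchange of sample names, the arrays with an undisputed group, the array splits and the permutation of list medians were tests chosen only after the result was seen. Counts of called genes are given for doxorubicin against control (25), the pre-treated against the doxorubicin group (9) and the pre-treated group against control (128), in that order. Series matrix values and names gave 0, 0 and 0 by limma (178, 349 and 361 at an unadjusted p under 0.05), and non-normalized signals under those names 0, 0 and 0 (164, 324 and 358). Series matrix values under the non-normalized names gave 12, 8 and 78, and the 7 arrays with an undisputed group 0 (732 at an unadjusted p under 0.05), 4 and 6, where the lone pre-treated array was assumed to vary like the other groups. Doxorubicin against control and the pre-treated group against control had 42 and 243 without background correction, 43 and 244 with the stricter detection filter (8082 genes tested), 39 and 213 with trend and robust settings, and 161 and 280 with array weights. Both array splits as covariates gave 225 in the pre-treated group against control and array split 1 gave 184. Replicate numbers were not taken to pair the mice. After group means were removed, 4 of 11 same-number pairs correlated over 0.1 (from -0.245 to 0.386). Pairs of unlike number were not compared, so pairing was not tested. The replicate number as a block gave 4, 64 (12 higher, 52 lower) and 210. Leaving out 1 array gave 3 (doxorubicin replicate 1) to 332 (doxorubicin replicate 2) in doxorubicin against control, 6 to 11 in the pre-treated against the doxorubicin group, and 25 (control replicate 3) to 294 (doxorubicin replicate 2) in the pre-treated group against control. The shift of doxorubicin-changed genes ran from -0.26 (without pre-treated replicate 2) to -0.017 (without doxorubicin replicate 4). It was 0.0808 with the doxorubicin arrays split 3 and 2, where the calls per split ran from 0 to 427. It had no value under the series matrix names or on the 7 arrays. The construction of trend and robust settings, weights and array splits changes the spread, and some settings tested fewer genes or arrays. Apart from these, the cause was not tested. All 25 genes of doxorubicin against control kept their sign under every setting not leaving out an array; in the others 2 of 9 and 27 of 128 changed sign under the series matrix values and names, and 1 of 9 and 22 of 128 under its names alone.

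Among the called genes followed one by one, the sign changed only under the series matrix names. For each such gene the series matrix value comes first, then, where 2 are given, that of the non-normalized signals. Against doxorubicin these were Vsig4 (-0.23, -0.055) and Tmem116 (-0.0029). Against control they were Vsig4 (-0.23, -0.10), S100a8 (-0.13), Rasl10a (-0.068, -0.072), Phlda3 (-0.11, -0.097), Ccl6 (-0.0066, -0.079), Icam1 (-0.032, -0.034) and Tmem116 (-0.10, -0.033). Of the called lists, 1 was called in the opposite direction, the macrophage list against control under those names (-0.26, -0.25). A list that changed direction and lost its call was counted only as having lost it. Of the called genes followed one by one, which were all 25, 8 of 9 and 30 of 128, those called whichever array was left out numbered 3, 5 and 10. An exact permutation of list medians could not call a list on its own after adjustment. Its smallest possible p (0.00794 with 252 splits, 0.0179 with 56) is too high for that. Unadjusted, the exact permutation test gave the interferon list p = 0.179 in the pre-treated against the doxorubicin group. In the pre-treated group against control the exact permutation test gave p = 0.232 (macrophage) and 0.339 (activin pathway). In doxorubicin against control the exact permutation test gave p = 0.167 (glucocorticoid) and 0.103 (smooth muscle). The other called lists had unadjusted p from 0.00794 to 0.0556 by the exact permutation test. A BeadChip block was not run. Signal over background limits genes detected on few arrays of a group; those detected on none of the lower group have only bounds.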

Other observations

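The tests of array splits as covariates and of macrophages as a source were chosen only after the result was seen.

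Circadian clock genes did not pass as a list after doxorubicin (14 genes, median -0.20, camera adjusted p = 0.288), and 0 were called by limma over all genes. Adjusted over the list alone 1 rose and 2 fell: Npas2, a partner of the core clock (at least 1.25-fold higher, detected on 0 of 5 control and 4 of 5 doxorubicin arrays), and the clock output genes Dbp (-1.99 ± 0.52, SE) and Nr1d1 (-1.01 ± 0.32). Of 14 endothelial markers, Eng, a coreceptor of the TGF-beta family, was higher in the pre-treated group than in controls (0.49 ± 0.11, adjusted p = 0.0424), and was called in 4 of the 13 fits that left out 1 array. Of 3 adipocyte markers, too few for a list test, Cidea (0.43 ± 0.10) and Pparg (0.55 ± 0.15) were higher in that comparison when adjusted over the list alone.

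The genes that differed with sAcvR2B-Fc included a macrophage gene that rose and a lymphatic chemokine that fell. With both array splits as covariates 7 of the 9 genes were called again (8 with split 1 alone). A median of 103% of their change was left (84.4 to 106%). The splits were drawn from the spread within groups, and genes are called where that spread is small. Little of the change could therefore be removed, so this test does not decide whether the array structure was the cause. Dipk1b went from 0.68 (SE 0.115) to 0.62 (SE 0.121, adjusted p = 0.143) and Tmem116 from 1.00 (SE 0.157) to 1.05 (SE 0.173, adjusted p = 0.0563), losing their calls with a larger SE. The median of 6 lymphatic markers was -0.176 (SE 0.132), from -0.632 (Mmrn1) to 0.057 (Lyve1). Pdpn stood at -0.438, Reln at -0.256, Flt4 at -0.0961 and Prox1 at -0.07. As far as these markers follow lymphatic endothelial cells, this argues against their loss as the whole cause of the fall in Ccl21a (-2.84). A smaller loss stays open. How much of each marker's signal came from such cells was not measured. The median of 15 macrophage markers was 0.193 (SE 0.0878), from -0.44 to 0.516, which argues against more macrophages as the whole cause. Both SEs were taken over the markers of a list, so they hold no spread between mice. An effect of sAcvR2B-Fc, the array structure, a difference in genetic background between mice, and a wrong sample name may each still account for these genes. These causes were not separated.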
